A study of Mus musculus with 28 samples.

How the data were processed

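Total RNA from left and right striatal punches, pooled per mouse, was measured on 28 Mouse Gene 1.0 ST arrays, per the labels and the column names of the deposited table. Drug-naive mice were used, and RNA was extracted with Trizol, passed over RNeasy columns, checked on a Bioanalyzer, amplified and labelled with biotin, per the labels' protocols. The deposited log2 values are RMA summaries per transcript cluster, the array's unit for a gene, made by the authors with Affymetrix Expression Console, per the submitters' processing notes, which give no versions. Probes over coding SNPs between B6 and A/J from 84 to 96 Mb of build 37 were masked during RMA with a kill list of Affymetrix Power Tools, per the deposited notes. The effect of the 2 batches was then removed with ComBat by the authors, per the deposited notes. The deposited p-values come from the authors' t-tests of 14 B6 against 14 congenic arrays, and the q-values from the QVALUE program, per the deposited notes. The q-value is missing for 8038 of 35556 clusters. Both deposited tables of log2 values agree within a maximum difference of 0.0, and 0 sample columns were unmatched.

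The values were used as deposited. Of the 35556 clusters, 21797 have 1 gene symbol in the platform annotation, 1613 have several and 12146 have none, and 0 symbols changed when updated through the gene ID. Genes were named from clusters with 1 symbol, taking for each gene the cluster with the highest mean over all arrays, which left 19946 genes. A position was found for 21691 of the clusters with 1 symbol. The A/J segment was taken by gene order along chromosome 11 of GRCm38.p6, from Acaca to Calcoco2, since no annotation of build 37 was at hand. The design text gives no chromosome, so chromosome 11 comes from knowledge of the study. The segment holds 264 reference genes, of which 132 were tested, and 50 reference genes on each side formed the flanks. The placing of its borders by gene order was not tested against coordinates of build 37. Listed as masked are 145 probes of 120 probesets, of which 1 has the ID of a cluster.

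Genes were tested with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. Carriers were compared with B6 mice over all 28 arrays with batch and sex as terms. The heterozygous, homozygous and sex comparisons and the difference of the 2 genotype effects came from 1 model of 4 group means and sex, and the effect of the segment by sex from a model with batch by sex. The number of arrays limits the precision. Calls in the segment were compared with those elsewhere by Fisher's exact test, with an exact 95% interval. The slope over segment genes is a total least squares slope through the origin, with an interval from 10000 resamples of genes, and its correlations were tested with 100000 permutations.

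Fixed before the data were examined were the designs, the settings to compare, the rule for named genes and 26 gene lists. To these came 4 lists by position, namely the segment, both flanks and the rest of chromosome 11. The lists cover dopamine signalling, spiny neuron classes, interneurons, neurons of neighbouring regions, choroid plexus, glia, vessels, blood, immediate early, glutamate and GABA receptor, circadian, glucocorticoid, cholesterol, heat shock, sex chromosome, ribosomal and oxidative phosphorylation genes. The 30 lists were tested with limma camera at a preset correlation of 0.01 and with camera at an estimated correlation. They were also tested with fry, for a shared direction (directional) and for changes in either direction (mixed). Each test was adjusted over the 30. Lists of hepatocyte, kidney, pancreas and skeletal muscle genes were added after liver genes had been seen among the leading genes of the first principal component. Samples of fewer than 10 values per group were compared by exact permutation tests.

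The rule named, for carriers against B6, up to 15 called genes inside the segment and 15 outside by smallest p with the same sign in both batches, and for the other genotype comparisons up to 8 inside and 8 outside. For sex and the effect by sex it named up to 8 genes. From each fixed list it named up to 6 members called over all genes or over the list alone. Drd1, Drd2, Slc6a3, Th, Ppp1r1b, Xist and Ddx3y were always to be named, of which Ddx3y is not among genes of a single-symbol cluster. Where a comparison called none, the 5 of smallest p were named as not passing.

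Each test was tried on simulated data for the 19946 genes with 200 changed genes. For carriers against B6 8.77%, 75% and 95.8% of genes changed by 0.1, 0.2 and 0.4 log2 were recovered with 12 false calls. For the heterozygous comparison the shares were 0%, 36.1% and 90.1% with 5 false calls, and for the homozygous one 0%, 41.7% and 94.4% with 7. At 0.4 log2, 97.5% of sex differences and 76.5% of differences between genotype effects were recovered. Simulated slopes of 1 and 2 over 132 genes came out at 0.946 (0.702 to 1.25) and 1.94 (1.61 to 2.23). There all 132 genes had heterozygous effects drawn with an SD of 0.1 log2, with independent noise. The authors' adjustment between batches was not simulated, so its bearing on the slope stays open.

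Alternatives tried were another quantile normalization, a filter at a mean log2 value of 6, all clusters of a gene, an intensity trend, array weights, no sex term, no batch term, age as a covariate, a block for the replicate number, each batch alone, the number of A/J alleles, thresholds of 0.01 and 0.1, segment limits moved by 10 genes, and leaving out each array in turn. Added after the data had been seen were the first principal component as a covariate, gene lists without B6 control 1, sex lists within each batch and without B6 control 1, hepatocyte genes by sex and by age, the methods' t-test on the same values, and leaving out clusters near masked probeset IDs. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. Clusters with several symbols or none were left out of the tests of genes, and a model over all 35556 clusters was fitted beside it.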

Results

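RNA from striatum was measured on 28 arrays, each from a different mouse, in a congenic strain that carries a segment of A/J chromosome 11 on a C57BL/6J (B6) background, and in B6 mice. The segment spans 84 to 96 Mb by the study's design. Batch 1 held 6 B6 and 6 heterozygous congenic mice, aged 41 to 68 days, which the labels call littermates, though heterozygous congenic 5, at 52 days, shares its age with no B6 mouse of the batch. Batch 2 held 8 B6 controls aged 61 to 63 days and 8 homozygous congenic mice aged 52 to 57 days, which were not littermates. Genotype, age and breeding therefore cannot be told apart there. The numbers in the array names of batch 2 also run in separate blocks by genotype, so any effect of that order cannot be told apart either. Each group held equal numbers of females and males, 3 of each in the batch 1 groups and 4 of each in the batch 2 groups. Median log2 values per array lay between 7.47 and 7.54. The median SD of a gene within a group was 0.0961 log2 units in littermates, 0.0946 in heterozygous mice, 0.109 in B6 controls and 0.0895 in homozygous mice. Xist, the RNA that silences one X chromosome in females, and the Y-linked gene Eif2s3y were on the side of the sex label in 28 of 28 arrays.

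Batch 2 arrays held liver transcripts in varying amounts. The mean of 27 hepatocyte genes was 8.09 ± 0.04 (SD, log2, n = 6) in littermates and 8.07 ± 0.07 (n = 6) in heterozygous mice, against 8.45 ± 0.90 (n = 8) in homozygous mice and 8.13 ± 1.66 (n = 8) in B6 controls. The authors had adjusted the batches to each other with ComBat, so the level of this mean cannot be compared between batches. The hepatocyte mean was 11.03 in B6 control 1, where all 27 genes had their highest value. Albumin (Alb) was at 11.40 there against a batch 2 median of 10.75, apolipoprotein A-I (Apoa1) at 12.01 against 9.93, the fatty acid binding protein Fabp1 at 10.72 against 7.96 and the cytochrome P450 Cyp2e1 at 11.41 against 8.60. Homozygous mice and B6 controls differed by 0.32 log2 in the hepatocyte mean (2-sided exact permutation test, p = 0.637), and heterozygous mice and littermates by -0.02 (exact permutation test, p = 0.597). Without B6 control 1 homozygous mice exceed B6 controls by more, and that difference was not tested. Striatal spiny neuron markers were lowest in B6 control 1, with a mean of 10.67 log2 against 11.07 to 11.34 in the other 7 B6 controls. The first principal component over arrays took 51.2% of the variance.

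**Figure D1:**
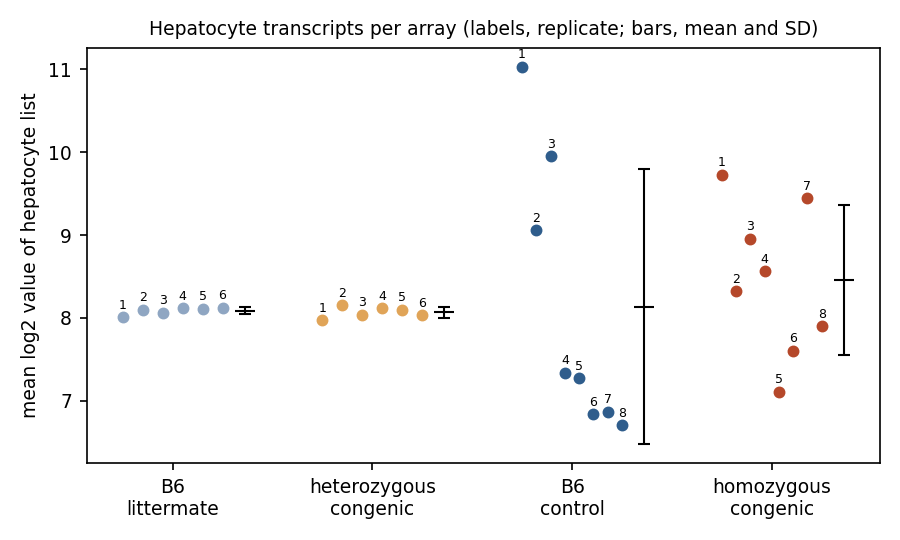
Mean log2 value of hepatocyte genes per array, by group, each point 1 mouse. The batch 1 arrays lie close together, and the batch 2 arrays spread from 6.71 to 11.03 with B6 control 1 highest.

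The main comparison asked which striatal genes differ between the 14 carriers of the A/J segment and the 14 B6 mice, a question posed for a chromosome segment linked to methamphetamine sensitivity. Cuedc1, which encodes a protein with a ubiquitin-binding CUE domain, was 1.22-fold higher in carriers (95% interval 1.15 to 1.29). Tob1, an antiproliferative protein of the BTG/Tob family, was lower at 0.846-fold, Brip1os, an RNA from the strand opposite Brip1, at 0.860-fold, and Mrpl27, a protein of the mitochondrial ribosome, at 0.895-fold. These 4 genes, 1 higher and 3 lower, were the calls among 19946 genes tested, and by their gene symbols all 4 lie in the A/J segment. Cuedc1 rose from 7.99 ± 0.12 (SD, log2) in littermates to 8.27 ± 0.06 in heterozygous mice, and from 7.97 ± 0.15 in B6 controls to 8.27 ± 0.07 in homozygous mice. Tob1 was at 9.30 ± 0.09 and 9.17 ± 0.10 in batch 1 and at 9.40 ± 0.05 and 9.08 ± 0.08 in batch 2. Brip1os was at 7.22 ± 0.11 and 6.98 ± 0.08 in batch 1 and at 7.19 ± 0.11 and 6.99 ± 0.07 in batch 2.

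By limma with batch and sex as terms, the log2 difference of Cuedc1 was 0.29 (SE 0.040, adjusted p = 0.00183), with 14 of 14 carriers above the B6 mean of their batch. The difference was -0.24 for Tob1 (SE 0.036, adjusted p = 0.0024) and -0.22 for Brip1os (SE 0.035, adjusted p = 0.00606), each lower in 14 of 14 carriers. Mrpl27 differed by -0.16 (SE 0.027, adjusted p = 0.0102), lower in 13 of 14 carriers, and the other array cluster of this gene gave -0.15. The ID of the Mrpl27 cluster used, 10454093, lies far from those of the other 3 called genes. That of its dimmer cluster, 10380411 (mean 6.30 log2), lies close to them. Genes were placed by symbol, and where the probes of the cluster used lie was not tested. At an unadjusted p under 0.05 stood 1058 genes, against 997.3 at that rate by chance. Leaving out heterozygous congenic 3 gave 7 calls, 5 in the segment and 2 outside it, 1700001P01Rik and Lpar4, a lysophosphatidic acid receptor gene. Leaving out B6 littermate 3 or homozygous congenic 7 added the microRNA gene Mir99a outside the segment, and leaving out B6 control 5 added 1700001P01Rik. Leaving out B6 control 1 gave 5 calls, all in the segment. Batch 1 alone gave 0 calls by limma and 876 genes at an unadjusted p under 0.05, with log2 differences of -0.13 for Tob1 and -0.12 for Mrpl27. Batch 2 alone gave 4, of which Tob1 was in the segment and 3 were olfactory receptor genes outside it, Olfr497, Olfr495 and Olfr168. These genes outside the segment fall outside the rule for named genes and were chosen after their values were seen.

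**Figure D2:**
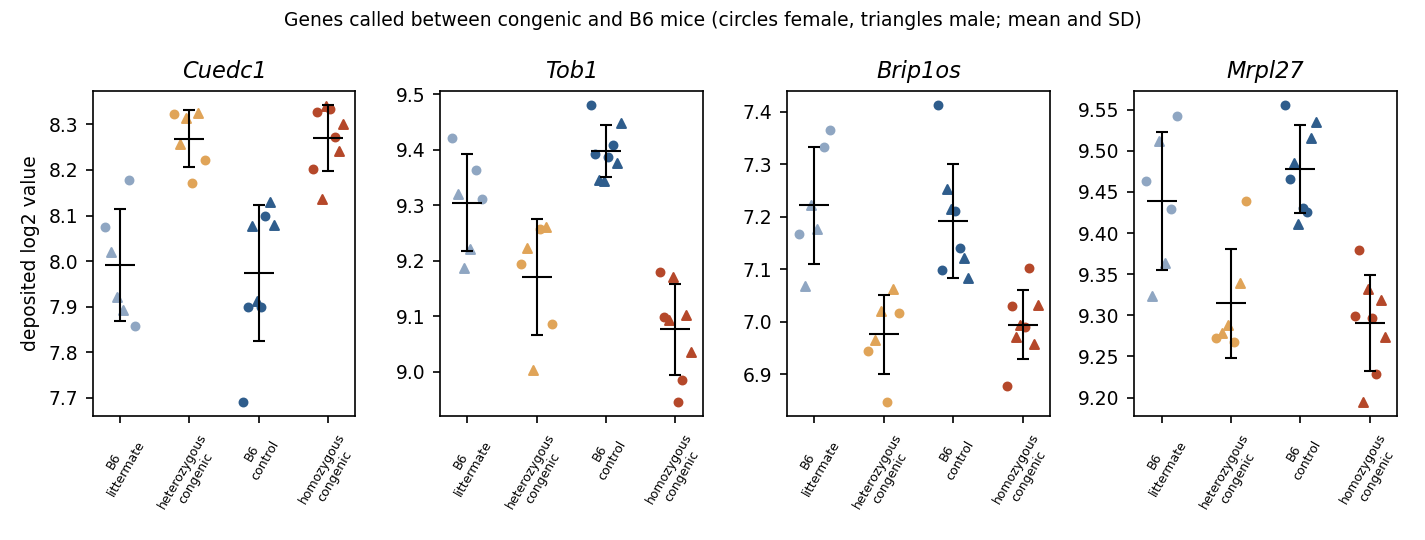
Log2 values of the 4 called genes in each mouse, by group, with the group mean and SD. Cuedc1 is higher, and Tob1, Brip1os and Mrpl27 lower, in carriers than in the B6 mice of the same batch.

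Genes of the A/J segment stood apart from the rest of the genome. Of the 132 segment genes tested, 9 were called when adjusted over the list alone, 3 higher and 6 lower. Beside the 4 above these were Tubd1 (delta-tubulin), higher by 0.13 log2 (SE 0.025, list adjusted p = 0.000607, 13 of 14 carriers), and Nme2, a nucleoside diphosphate kinase, at -0.19 (SE 0.043, list adjusted p = 0.00324, 14 of 14). The other 3 fall outside the rule for named genes and were chosen after their values were seen. Rsad1, of the radical SAM enzyme family, was at 0.15 (SE 0.037, list adjusted p = 0.00425, 14 of 14). The mitochondrial ribosomal protein gene Mrps23 was at -0.11 (SE 0.030, list adjusted p = 0.0206, 14 of 14), and Dgke, a diacylglycerol kinase, at -0.21 (SE 0.059, list adjusted p = 0.0225, 14 of 14). With age as a covariate Mrps23 had a list adjusted p of 0.0518. In batch 1 alone, Tob1, Mrpl27, Tubd1, Nme2 and Mrps23 each had a list adjusted p of 0.266 and Rsad1 one of 0.444. In batch 2 alone, Nme2 had one of 0.0501, Mrps23 of 0.40 and Dgke of 0.470. Without B6 control 1, 15 segment genes were called, including all 9.

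At an unadjusted p under 0.05 stood 27 of the 132 segment genes (20.5%) and 1020 of 19719 genes elsewhere (5.17%), an odds ratio of 4.71 (95% interval 2.95 to 7.29, Fisher's exact test, p = 1.05e-09). Of these 27 segment genes 16 were higher and 11 lower in carriers. For calls over all genes the counts were 4 of 132 and 0 of 19719, an odds ratio above 100 (lower 95% bound, Fisher's exact test, p = 1.87e-09). That bound was 60.1 without B6 littermate 3, homozygous congenic 7 or B6 control 5, 62.4 without heterozygous congenic 3, 0 in batch 1 alone and 0.948 in batch 2 alone. It was 3.83 with the replicate number as a block, where Cuedc1 alone was called, 36.5 without clusters near masked probesets and 62.3 by number of A/J alleles. Within batches at an unadjusted p under 0.05, the odds ratio was 3.16 in batch 1 (14 of 132 segment genes, Fisher's exact test, p = 0.000354) and 2.40 in batch 2 (18 of 132, p = 0.00161 by the same test). Past the distal end of the segment, 2 of 27 genes tested were called when adjusted over the list alone. These were Copz2, a subunit of the coatomer of vesicle transport, at -0.17 log2 (SE 0.045, 14 of 14 carriers), and Osbpl7, of the oxysterol-binding protein family, at -0.14 (SE 0.035, 13 of 14), both with a list adjusted p of 0.00931. Over all genes their adjusted p was 0.615 and 0.63, and the list adjusted p of both was 0.0615 with age as a covariate. In batch 1 alone both had a list adjusted p of 0.551. Past the proximal end, limma called 0 of 23 genes, and 0 had an unadjusted p under 0.05. On the rest of chromosome 11, 0 of 1381 genes were called by limma and 62 had an unadjusted p under 0.05.

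**Figure D3:**
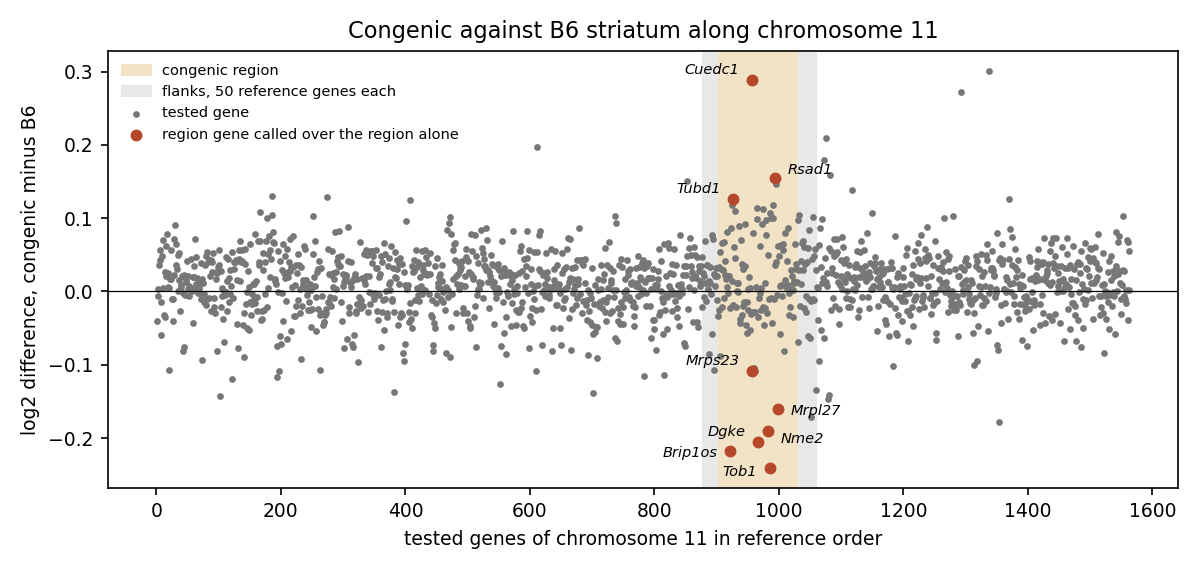
Log2 difference between carriers and B6 mice for genes in order along chromosome 11, with the A/J segment marked. The called genes, from Brip1os to Tob1 and Mrpl27, lie inside it.

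Striatal neuron classes showed no called member between carriers and B6 mice. Drd1, the dopamine D1 receptor, differed by 0.03 log2 (SE 0.049) and Drd2, the D2 receptor, by -0.003 (SE 0.052). The dopamine transporter gene Slc6a3 differed by 0.01 (SE 0.041), Th, which makes the dopamine precursor, by -0.002 (SE 0.059), and Ppp1r1b, which encodes DARPP-32, by -0.02 (SE 0.054). By limma camera, adjusted p was 0.701 for dopamine signalling (11 of 19 genes higher), 0.399 for direct-pathway spiny neuron markers (5 of 9 lower), 0.706 for indirect-pathway markers (4 of 8 higher) and 0.91 for shared spiny neuron markers (13 of 17 higher). It was 0.305 for striatal interneurons (9 of 14 lower), 0.399 for cortical excitatory neurons (8 of 11 higher), 0.0652 for thalamic and subcortical excitatory neurons (6 of 9 lower) and 0.219 for septal, pallidal and hypothalamic markers (8 of 11 lower). For other cells it was 0.701 for choroid plexus and ependyma (7 of 12 higher), 0.85 for oligodendrocytes (9 of 12 higher), 0.66 for their precursors (6 of 8 higher), 0.908 for astrocytes (6 of 12 lower), 0.91 for microglia (7 of 12 lower), 0.0652 for endothelium and pericytes (9 of 12 lower) and 0.91 for blood cells (3 of 4 higher). It was 0.91 for GABA-A receptors and GABA synthesis (11 of 16 higher), 0.91 for circadian genes (12 of 17 higher), 0.458 for cholesterol synthesis (11 of 17 lower), 0.572 for heat shock and chaperone genes (13 of 20 lower), 0.91 for Y-linked genes (1 of 3 lower) and 0.701 for X inactivation and escape genes (2 of 5 lower). It was 0.706 for the segment (79 of 132 higher) and for the distal flank (15 of 27 higher), 0.582 for the proximal flank (17 of 23 higher) and 0.706 for the rest of chromosome 11 (858 of 1381 higher). The median was above 0 while the test pointed down for dopamine signalling, astrocytes, Y-linked genes and X inactivation and escape genes. Without B6 control 1 several of these directions turned. Shared spiny neuron markers were then lower in 16 of 17 (camera, adjusted p = 0.0940) and dopamine signalling genes in 13 of 19 (0.332). Oligodendrocyte markers were then lower in 8 of 12 (adjusted p = 0.352) and cholesterol synthesis genes higher in 14 of 17 (0.175).

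Of the 30 lists, 5 shifted in carriers by camera with a preset correlation. Immediate early genes, which neurons transcribe upon activity, were lower in 15 of 18 members (adjusted p = 6.03e-05, and adjusted p = 0.673 with an estimated correlation), with Npas4 at -0.48 log2, Fos at -0.19 and Btg2 at -0.15. Glucocorticoid-responsive genes were lower in 13 of 15 (adjusted p = 0.00363, and adjusted p = 0.673 with an estimated correlation), with Sgk1 at -0.19 and Mt1 at -0.10. Ribosomal protein genes were lower in 38 of 57 (adjusted p = 0.00363) with a median of -0.02, and oxidative phosphorylation genes in 51 of 77 (adjusted p = 0.000172), also with a median of -0.02 (both adjusted p = 0.673 with an estimated correlation). Glutamate receptor genes were higher in 20 of 22 (adjusted p = 0.0344, and adjusted p = 0.960 with an estimated correlation) with a median of 0.04. In heterozygous mice alone, immediate early genes were higher in 10 of 18 (median 0.03, adjusted p = 0.892) and glutamate receptors lower in 12 of 22 (median -0.005, adjusted p = 0.892). Glucocorticoid-responsive genes were lower there in 8 of 15 (adjusted p = 0.455) and ribosomal protein genes in 33 of 57 (0.319). Oxidative phosphorylation genes were lower there in 56 of 77 (adjusted p = 0.00667, and adjusted p = 0.991 with an estimated correlation). No member of these 5 lists was called, over all genes or over the list alone. All 5 calls were thus lost with an estimated correlation. By limma fry's directional test the smallest adjusted p of any list was 0.819. Its mixed test, which counts changes in either direction, gave adjusted p = 0.00338 for the distal flank and 0.00492 for the segment. Without B6 control 1, immediate early (adjusted p = 9.65e-05), glucocorticoid-responsive (0.0209) and oxidative phosphorylation genes (0.0310) were still called and glutamate receptors (0.486) and ribosomal protein genes (0.240) were not. That setting added direct-pathway spiny neuron markers, lower in 8 of 9 (adjusted p = 0.0381), and all 4 of its calls had adjusted p = 0.758 with an estimated correlation.

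Mice with a single A/J copy were set against the B6 littermates of batch 1, and litter was not a term of the model. Brip1os was lower at 0.844-fold (log2 -0.25, SE 0.054) and Cuedc1 higher at 1.21-fold (log2 0.28, SE 0.063), each in 6 of 6 heterozygous mice. Slc17a6, which loads glutamate into the vesicles of thalamic and other subcortical neurons, was at 6.40 ± 0.16 (SD, log2, n = 6) against 6.81 ± 0.42 (n = 6), a fold of 0.750 (log2 -0.42, SE 0.126) and lower in 6 of 6. By limma 0 genes were called over all genes, 735 had an unadjusted p under 0.05, and the smallest adjusted p was 1.00. Dynlrb2, at 0.19, Syna, at 0.25, and Try10, at 0.30 log2, followed Brip1os and Cuedc1 by p and did not pass. Over the segment alone Brip1os and Cuedc1 were called, each with a list adjusted p of 0.00969, and without B6 control 1 there were 5 segment calls, including both.

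All 9 thalamic and subcortical excitatory neuron markers were lower in heterozygous mice (camera, adjusted p = 0.00483, and adjusted p = 0.188 with an estimated correlation), with Slc17a6 called over the list alone (list adjusted p = 0.024). Oxidative phosphorylation genes were lower in 56 of 77 (adjusted p = 0.00667, and adjusted p = 0.991 with an estimated correlation), with 0 members called by limma and 1 at an unadjusted p under 0.05. By fry's directional test the smallest adjusted p of any list was 0.407. The list adjusted p of Slc17a6 was 0.0625 without B6 littermate 2 and 0.118 without B6 littermate 5. It was 0.0517, 0.0656 and 0.0910 without heterozygous congenic 1, 2 and 4, and 0.0633 with no sex term.

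Mice with both copies from A/J were set against B6 controls. Tob1 was lower in 8 of 8 homozygous mice, at 0.800-fold (log2 -0.32, SE 0.042, adjusted p = 0.000556), the 1 gene called over all genes by limma, while 1244 had an unadjusted p under 0.05. Within the segment, 7 genes were called over the list alone, all in 8 of 8 mice. Beside Tob1 these were Cuedc1 at 0.30 log2 (SE 0.054, list adjusted p = 0.000599), Mrpl27 at -0.19 (SE 0.035, 0.000599), Brip1os at -0.20 (SE 0.046, 0.00669), Rsad1 at 0.20 (SE 0.048, 0.00669) and Tubd1 at 0.13 (SE 0.033, 0.0128). Nme2, at -0.21 (SE 0.058, list adjusted p = 0.0220), falls outside the rule for named genes and was chosen after its values were seen. Its list adjusted p was 0.0608, 0.0669 and 0.0547 without homozygous congenic 3, 6 and 8, and 0.0679 without B6 control 3. Tubd1 had one of 0.0666 after another quantile normalization. Without B6 control 1 there were 11 segment calls, including all 7. Over all genes, leaving out B6 littermate 5, homozygous congenic 3, B6 control 6 or B6 control 7 gave 2 calls each, Tob1 and Cuedc1. Past the distal end Osbpl7, at -0.18 (SE 0.046, list adjusted p = 0.0120), and Copz2, at -0.22 (SE 0.059, 0.0125), were lower in 8 of 8, and Copz2 had a list adjusted p of 0.0815 with age as a covariate.

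Immediate early genes were lower in 17 of 18 members in homozygous mice (camera, adjusted p = 1.34e-08, and adjusted p = 0.467 with an estimated correlation). Npas4 fell to 0.601-fold, from 8.92 ± 0.30 to 8.19 ± 0.44 (SD, log2, n = 8 each), and Fos to 0.827-fold, from 7.44 ± 0.14 to 7.16 ± 0.16, both in 8 of 8 mice. Their log2 differences were -0.73 (SE 0.220) and -0.27 (SE 0.084), with a list adjusted p of 0.0262 for both and 0.170 for both with age as a covariate. The list adjusted p of both was 0.0715, 0.0527 and 0.0797 without homozygous congenic 5, 6 and 7, and 0.0505, 0.0536 and 0.0744 without B6 control 2, 6 and 8. Fos had one of 0.0648 without homozygous congenic 8. Endothelial and pericyte markers were lower in 12 of 12 (adjusted p = 0.000789, and adjusted p = 0.335 with an estimated correlation), with a median of -0.05. Glucocorticoid-responsive genes were lower in 13 of 15 (adjusted p = 0.00591, and adjusted p = 0.467 with an estimated correlation), and cholesterol synthesis genes in 11 of 17 (adjusted p = 0.0407, and adjusted p = 0.995 with an estimated correlation). Ribosomal protein genes were lower in 37 of 57 (adjusted p = 0.0176) and oxidative phosphorylation genes in 48 of 77 (adjusted p = 0.0283), both with adjusted p = 0.951 with an estimated correlation. Glutamate receptor genes were higher in 21 of 22 (adjusted p = 0.0016, and adjusted p = 0.951 with an estimated correlation), with a median of 0.08. By fry's directional test the smallest adjusted p of any list was 0.616. By its mixed test adjusted p was 0.117 for the distal flank and 0.133 for the segment. Without B6 control 1, immediate early (17 of 18, adjusted p = 1.04e-09), endothelial (0.0183) and glucocorticoid-responsive genes (0.0114) were still lower. Glutamate receptors (0.414), cholesterol synthesis (0.557), ribosomal protein and oxidative phosphorylation genes (0.590 each) were then not called. In their place shared spiny neuron markers were lower in 17 of 17 (adjusted p = 0.000123) and direct-pathway markers in 9 of 9 (0.0025), and choroid plexus and ependymal markers were higher in 10 of 12 (0.0429). These 3 had adjusted p = 0.806, 0.638 and 0.896 with an estimated correlation, in that order, and the 3 lists still called had adjusted p = 0.638 with an estimated correlation. B6 control 1 also had the highest hepatocyte mean (11.03). Leaving it out widens the excess of that mean in homozygous mice (8.45) over B6 controls (8.13 with all 8). Its part in the shifts of these 3 lists was not tested.

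Effects in the 2 batches, which share no arrays, correlated over the segment. Tob1 differed by -0.13 log2 with 1 A/J copy and by -0.32 with 2, while Cuedc1 differed by 0.28 and 0.30 and Brip1os by -0.25 and -0.20. Across the 132 segment genes the slope of homozygous on heterozygous effects was 0.965 (95% interval 0.677 to 1.30), where additive alleles would give 2. It was 1.03 without the 2 genes farthest on the heterozygous axis and 0.797 without the 5 of smallest p. Noise in both effects enters this slope. The simulated slopes gave all 132 genes an effect, while 9 segment genes were called between carriers and B6. The slope therefore cannot exclude additive alleles. Pearson's r across genes was 0.553 and Spearman's rho 0.423 (permutation p = 1e-05 each, the smallest that 100000 permutations can give), and genes are not independent replicates. Pearson's r was 0.524 without the 2 genes farthest out and 0.425 without the 5 of smallest p, and -0.03 over genes outside the segment. The sign was shared by 78 of 132 segment genes (59.1%). For the difference of the 2 effects limma called 0 genes, with 1011 at an unadjusted p under 0.05. The smallest p belonged to the olfactory receptor genes Olfr146 (-0.43 log2), Olfr689 (-0.39), Olfr495 (-0.51) and Olfr619 (-0.42) and to Try10 (-0.47), which did not pass (smallest adjusted p = 0.510). The comparison also differs by batch, age and breeding, and both batches had been adjusted to each other before deposit, per the deposited notes.

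**Figure D4:**
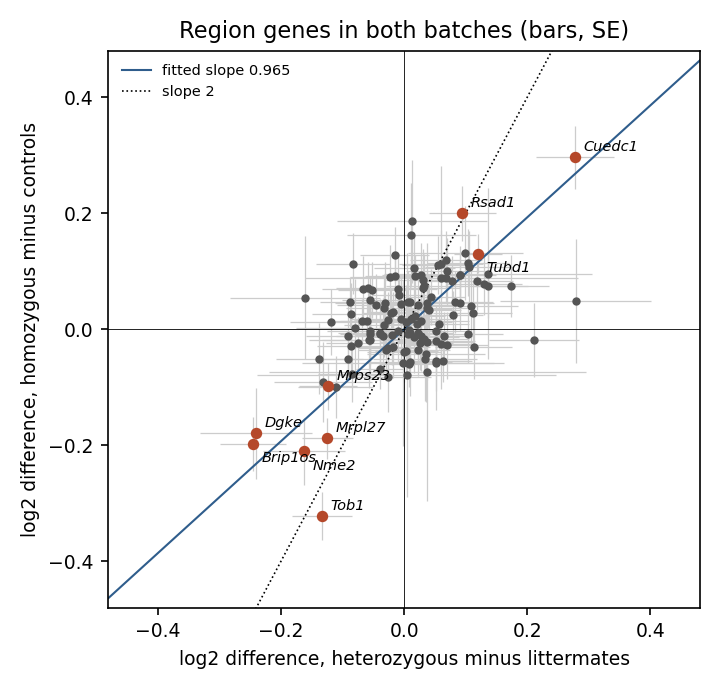
Log2 effect in homozygous mice against that in heterozygous mice for segment genes, with SE bars, the fitted slope of 0.965 and a dotted line of slope 2. Cuedc1 and Brip1os lie near the fitted line and Tob1 nearer the line of slope 2.

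Males and females differed in genes of the sex chromosomes. Eif2s3y, which encodes a translation initiation factor subunit, was at least 22.6-fold higher in males, Uty at least 12.1-fold and Kdm5d, a histone demethylase gene, at least 6.02-fold. Females lack these Y-linked genes, so their values (4.76, 4.98 and 5.99 log2) are probe background and the folds are lower bounds. Xist was at 11.94 ± 0.25 (SD, log2, n = 14) in females and 7.75 ± 0.79 (n = 14) in males (difference -4.19, SE 0.213, limma adjusted p = 7.56e-14). The X-linked genes Eif2s3x (-0.45 log2), Kdm6a (-0.33), Ddx3x (-0.27) and Kdm5c (-0.16, adjusted p = 0.00467) were lower in males, and the multi-copy Y gene Srsy was higher by at least 1.03. In all 11 genes were called by limma, 6 higher and 5 lower in males, and 1464 had an unadjusted p under 0.05.

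Spiny neuron markers were higher in males than in females by camera with a preset correlation, which called 14 of the 30 lists. All 17 shared markers were higher (camera, adjusted p = 2.52e-13, and adjusted p = 0.181 with an estimated correlation), 10 of them called over the list alone. Lrrc10b differed by 0.23 log2, Rasgrp2 by 0.19, Gng7 by 0.15, Pde1b by 0.14, Ptpn5 by 0.13 and Meis2 by 0.12, each with a list adjusted p of 0.0310. Direct-pathway markers were higher in 8 of 9 (adjusted p = 1.15e-05) and indirect-pathway markers in 7 of 8 (0.000159), both with adjusted p = 0.178 with an estimated correlation. Among them the transcription factor gene Ebf1 was at 0.23 (list adjusted p = 0.00284), the muscarinic receptor gene Chrm4 at 0.17 and Drd1 at 0.15 (0.0206 each), Isl1 at 0.12 (0.0401), Drd2 at 0.16 and Gpr6 at 0.21 (0.0244 each). Over all genes none of these list members was called by limma. Dopamine signalling genes were higher in 14 of 19 (adjusted p = 0.000415, and adjusted p = 0.185 with an estimated correlation). Fry's directional test gave adjusted p = 0.113 for shared, 0.101 for direct-pathway and 0.101 for indirect-pathway markers, and 0.131 for dopamine signalling, so none of these was called by it. B6 control 1, a female, had the lowest spiny marker mean of the B6 controls, and without it shared markers were higher in 16 of 17 (camera, adjusted p = 6.63e-12). Their median was then 0.08 log2, against 0.12 over all arrays. In batch 1 alone, whose arrays differ little in liver transcripts, they were higher in 16 of 17 (adjusted p = 7.11e-06), and in batch 2 alone in 17 of 17 (1.26e-09). These settings were run with the preset correlation alone. Hepatocyte genes averaged 8.06 ± 0.06 in females and 8.10 ± 0.04 in males of batch 1 (n = 6 each, exact permutation test, p = 0.279, adjusted 0.558), and 8.37 ± 1.47 and 8.22 ± 1.21 in batch 2 (n = 8 each, exact permutation test, p = 0.818). Without B6 control 1, at 11.03, the batch 2 female mean falls below that of males, which was not tested.

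Other lists were also called by sex with a preset correlation. Cortical excitatory neuron markers were lower in males in 11 of 11 (adjusted p = 0.00113, and adjusted p = 0.477 with an estimated correlation), with 9 of 11 lower in batch 1 alone and 11 of 11 in batch 2 alone. Immediate early genes were lower in 16 of 18 (adjusted p = 0.00113, and adjusted p = 0.478 with an estimated correlation), and heat shock and chaperone genes in 17 of 20 (adjusted p = 0.000954, and adjusted p = 0.181 with an estimated correlation). Within batches these 2 lists were called in batch 1 (18 of 18 and 17 of 20 lower) and not in batch 2 (adjusted p = 0.268 and 0.414). Circadian genes were higher in 12 of 17 (adjusted p = 0.000336, and adjusted p = 0.264 with an estimated correlation), among them the clock gene Per2 at 0.15 (list adjusted p = 0.00498), Tef at 0.15 and Cry2 at 0.11 (0.0377 each), and Per3 at 0.14 (0.0467). Cholesterol synthesis genes were lower in 15 of 17 (adjusted p = 0.00175, and adjusted p = 0.478 with an estimated correlation), with a median of -0.08. Without B6 control 1 the median was -0.02 and the call was lost (13 of 17 lower, adjusted p = 0.171), while within each batch 15 of 17 were lower (adjusted p = 0.00216 and 0.0329). Oligodendrocyte markers were higher in 11 of 12 (adjusted p = 0.00808, and adjusted p = 0.486 with an estimated correlation) and microglia markers in 10 of 12 (adjusted p = 0.0170, and adjusted p = 0.452 with an estimated correlation). In batch 1 alone oligodendrocyte markers went the other way, lower in 8 of 12 (adjusted p = 0.296), and microglia markers were higher in 8 of 12 (0.582), while in batch 2 alone both were higher in 11 of 12 (1.66e-05 and 0.0103). Without B6 control 1 neither was called (8 of 12 higher, adjusted p = 0.143, and 10 of 12 higher, 0.0545). Distal flank genes were lower in 19 of 27 (adjusted p = 0.0374, and adjusted p = 0.477 with an estimated correlation). They were higher in 14 of 27 in batch 1 alone (adjusted p = 0.490) and lower in 19 of 27 in batch 2 alone (0.0356), and the call was lost without B6 control 1 (20 of 27 lower, 0.143) and with the first principal component as a covariate (0.113). Differences between the batches in these shifts were not tested. Slc17a6 was lower in males at -0.25 (list adjusted p = 0.0473). The Y-linked (3 of 3 higher) and X lists (5 of 5 lower) were called with a preset and with an estimated correlation (adjusted p = 3.05e-09 and 6.80e-09 with an estimated correlation).

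Several of these sex calls lay near the threshold, where leaving out 1 array ended them while the direction stayed. The list adjusted p of Lrrc10b, Rasgrp2, Gng7, Pde1b, Ptpn5 and Meis2 lay between 0.0507 and 0.0640 without homozygous congenic 5, 6, 7 or 8 or B6 control 8. Tef had one between 0.0516 and 0.0719 without B6 littermate 2, heterozygous congenic 3, homozygous congenic 8, or B6 control 7 or 8. Cry2 had one between 0.0516 and 0.0777 without any of those 5 arrays or B6 littermate 1 or 6. Isl1 lost its call, with a list adjusted p between 0.0511 and 0.0832, without B6 littermate 1, heterozygous congenic 1, 2, 3, 5 or 6, homozygous congenic 2, 3, 5, 6, 7 or 8, or B6 control 1, 3, 6 or 8. Per3 lost it, at 0.0531 to 0.0904, without any B6 littermate, heterozygous congenic 1, 2 or 3, homozygous congenic 1, 2, 3, 7 or 8, or B6 control 1, 2, 7 or 8. Slc17a6 lost it, at 0.0568 to 0.10, without B6 littermate 3, 4, 5 or 6, heterozygous congenic 1, 2 or 6, homozygous congenic 2, 3, 5, 6, 7 or 8, or B6 control 1, 2, 3, 6 or 7.

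The effect of the segment was compared between the sexes. Mir382 (log2 difference of effects, male minus female, -0.39), Plscr4 (0.26), Adamts6 (0.25), Igfbp6 (-0.40) and Mir136 (-0.39) had the smallest p and did not pass. By limma 0 genes were called, 961 had an unadjusted p under 0.05, and the smallest adjusted p was 0.962. In simulated data on the 19946 genes, 77.5% of genes with a difference of effects of 0.4 log2 were recovered.

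In the authors' own deposited table, 13 array clusters had a q-value under 0.05, 4 higher and 9 lower in carriers. With 1 symbol stood 7 of them, Cuedc1, Tob1, Brip1os, Tubd1, both Mrpl27 clusters and Prkag1, a subunit of AMP-activated kinase outside the segment (mean difference -0.08, q = 0.0116). Prkag1 was not called here by limma (adjusted p = 0.353), while the methods' t-test on the same values gave it an adjusted p of 0.0128, so the gap lies in the model and not in the values.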

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

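The tests of liver transcripts other than that of the spiny marker mean, of segment genes that were higher, and of genes past the distal end were chosen after the result was seen, and those of lower segment genes and of other splits of the samples before.

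Liver transcripts varied among batch 2 arrays. Over the 27 measured hepatocyte genes the median range was 4.61 log2 in batch 2 and 0.724 in batch 1, against 0.326 for skeletal muscle, 0.438 for kidney and 0.333 for pancreas lists in batch 2, and none of the 27 is in another list. Array-wide noise or scaling is argued against, since the widest of 10000 random lists matched on mean expression ranged over 0.630. Another tissue hybridised in place of striatum for B6 control 1 is argued against, since none of its 17 shared spiny markers lay farther than -0.764 log2 from the median of the other B6 controls, while RNA of another tissue alone would lack them. Their mean lay -0.61 log2 from that median, between both bounds written beforehand. RNA from liver in some striatal samples may be the source, as a hypothesis on the same data, and no biological explanation was tested.

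Segment genes at an unadjusted p under 0.05 were higher in carriers in 59.3% (16 of 27, exact 95% interval 38.8 to 77.6). SNPs under unmasked probes, which lower hybridisation of the A/J allele, are argued against for the higher genes by that share. For lower genes such as Tob1 they cannot be told apart from a lower RNA level. Outside the ID block of masked probesets 6 genes were lower and 7 higher, and inside it 5 and 9 (Fisher's exact test, p = 0.704), and that block is only a proxy. Regulatory variants of the A/J segment stay open, untested.

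Past the distal end of the segment, carriers differed in Copz2, Osbpl7 and others. The mean squared t of these 27 genes exceeded 99.8% of runs of as many genes on other chromosomes, and their heterozygous and homozygous effects correlated (r = 0.599 across genes, permutation p = 0.00083), in line with a donor segment longer than stated. SNPs under probes not searched for masking are argued against for the higher genes, which made up 71.4% of those at an unadjusted p under 0.05 (5 of 7, exact 95% interval 29 to 96.3; Ttll6, Hoxb7, Hoxb3, Cbx1 and Sp6). For the lower genes they cannot be told apart from a lower RNA level, since the 2 called genes without a listed masked probeset would be so either way. Effects of the segment on neighbours, the border set by gene order, and, in batch 2, age and breeding stay open, untested.

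Other splits of the samples were drawn, 100 each with the real one included, and their shares were not adjusted for the number of counts tested. The 4 genes called between carriers and B6 (highest other split 1) and the 9 segment genes (highest other 3) were both reached by 1 split, the real one, which argues against chance. The same holds for the 7 homozygous segment genes (1 split, highest other 3) and the 11 genes called by sex (1 split, highest other 1). The 2 heterozygous segment genes were reached by 2 splits (highest other 2). That share lay under the bound written beforehand, but another split matched the count, so chance is not excluded. The 1 gene called between homozygous mice and B6 controls was reached by 3 splits, also under that bound, which does not exclude chance. The highest other split there called 782 genes. That split had the largest hepatocyte difference of the 100, 1.87 log2, a structure of the samples. Where the real count was 0 every split reaches it by definition (100 of 100), so the splits say nothing about chance in the heterozygous comparison (highest other 0), the difference of effects (highest other 3) and the effect by sex (highest other 1).

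Single samples stood apart from their groups in 12 of 200 groups of named genes tested, where chance gives about 1 in 20, and 7 of the 12 were B6 control 1. The gap to the nearest sample as a share of the group's range was 0.691 for Ebf1, 0.579 for Drd2, 0.606 for Meis2, 0.618 for Pde1b, 0.707 for Tef, 0.664 for Cry2 and 0.701 for Ppp1r1b, all lowest in B6 control 1. It was 0.817 for Mir382 (heterozygous congenic 5 lowest), 0.555 for Tubd1 (B6 control 2 highest) and 0.762 for Rsad1 (B6 littermate 5 lowest). It was 0.719 for Ptpn5 (heterozygous congenic 2 highest) and 0.634 for Slc6a3 (B6 littermate 4 highest).

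Among all 35556 clusters limma called 9, the 4 named genes and 5 clusters outside the tests of genes. Without a symbol are cluster 10340572, at -0.84 log2 (SE 0.079, adjusted p = 1.45e-06), cluster 10338327, at -0.43 (SE 0.069, adjusted p = 0.00565), and cluster 10390299, at -0.34 (SE 0.051, adjusted p = 0.00209). With several symbols, at least one of them in the segment, are cluster 10422776, at 0.29 (SE 0.030, adjusted p = 2.98e-06), and cluster 10380551, at 0.23 (SE 0.026, adjusted p = 2.50e-05).

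A score from segment genes chosen without the array in question was on the side of the genotype label in 27 of 28 arrays. The exception was B6 control 1, at 0.11 on the congenic side with 15 genes. In it 4 of 4 called genes and 7 of 9 segment genes called over the list alone lay on the B6 side. Those genes were chosen with this array counted as B6, so that count cannot check its label.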

How the results depend on the processing

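Added after seeing the data were the first principal component as a covariate, the methods' t-test, leaving out clusters near masked probesets, genotype lists without B6 control 1, and the settings of sex lists; the other settings given here were planned, and were carried over to the segment counts after seeing the data. The 4 genes called between carriers and B6 became 0 in batch 1 alone (limma, 876 genes at an unadjusted p under 0.05) and 2 without clusters near masked probesets, which removes tested genes, and lay between 4 and 7 when each array was left out. They were 6 with array weights, all in the segment, 6 by the methods' t-test after Benjamini-Hochberg adjustment (5 in the segment, and Prkag1), 3 at a threshold of 0.01 and 5 at 0.1. The 1 homozygous call, Tob1, became 2 in the segment after quantile normalization and with age. It became 3 with array weights (Osbpl7 outside the segment), 4 from batch 2 arrays alone (Olfr497, Olfr495 and Olfr168 outside), 3 with the first principal component (Bhmt outside) and 0 without clusters near masked probesets (1 to 2 leaving out arrays). Genes outside the segment were named after their values were seen. The 9 segment calls became 15 with array weights, 5 in batch 1 alone and 21 with the first principal component (9 to 15 leaving out arrays). The 2 heterozygous segment calls became 5 from batch 1 arrays alone, 5 with the first principal component and 1 without clusters near masked probesets (2 to 5). The 7 homozygous ones became 12 with array weights (6 to 11). The odds ratio's lower bound was 0 in batch 1 alone, where nothing was called (60.1 to 140 leaving out arrays). Calls by sex were 31 over all clusters of a gene, which counts copies of Srsy, and 9 to 13 leaving out arrays. The heterozygous, difference and by-sex counts stayed at 0 leaving out arrays, and the slope lay between 0.811 and 1.10. With an estimated correlation, lists called fell to 0, 0 and 0 in the genotype comparisons and to 2 by sex; sex lists called were 13 in batch 1 alone, 15 in batch 2 alone, 14 with the first principal component and 11 without B6 control 1. The cause of the other changes was not tested.

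With the replicate number as a block, carriers against B6 gave 1 call, the homozygous comparison 3 (Olfr495 and Olfr488 outside the segment) and the difference of effects 1. Numbers did not pair the samples throughout, and not every array correlated best with its own number. Same-number correlations ran from -0.17 to 0.11 in batch 1. In batch 2 they were 0.64, 0.36, 0.12, 0.61, 0.65 and 0.48 for numbers 1, 3, 4, 5, 6 and 8, and -0.12 and -0.65 for 2 and 7. There the number follows sex and the older and younger mice in the same order in both groups, so the block may hold shared structure.

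Of the values for single genes by genotype, 955 kept direction and side of the threshold and 44 kept direction alone; by sex, 785 and 99 did. None reversed. Not run were a filter on detection p-values, which no file here holds, and leaving out masked clusters by ID, void with 1 of 120 IDs matching; the other deposited values were identical. Signal over background limits dim genes, for which no background values were analysed here.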

Other observations

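The tests below were chosen after the data had been seen. Olfactory receptor genes, which are dim here with a median level of 5.44 log2, were lower in homozygous mice than in B6 controls in 869 of 1027 genes, with a median of -0.07 log2. Of the 316 at an unadjusted p under 0.05, 314 were lower, and limma called 0 (Olfr497, Olfr495 and Olfr168 when fitted to batch 2 arrays alone). Their mean per array was 5.47 ± 0.05 (SD, n = 8) in homozygous mice and 5.56 ± 0.03 (n = 8) in B6 controls (exact permutation test, p = 0.00171, adjusted 0.00342 over 2 comparisons). In heterozygous mice 314 of 1027 were lower, with a median of 0.03, 65 at an unadjusted p under 0.05 and 58 of these higher (exact permutation test of the mean per array, p = 0.370), with 0 called by limma. Vomeronasal receptor genes were lower in 136 of 167 in homozygous mice, and all 33 at an unadjusted p under 0.05 were lower, with 0 called by limma. The 2275 other genes with a mean under 6 had a median of -0.003 in homozygous mice.

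In windows of 20 neighbouring genes, the highest mean squared t between carriers and B6 was 7.71, from Nme2 to Gm11541 in the segment, reached by 0 of 100 shuffles of gene order. Away from segment and flanks it was 4.51, from Mrpl45 to Cacnb1 on chromosome 11, reached by 8 of 100. In heterozygous mice it was 3.13, from Srsf1 to Mmd (6 of 100), and in homozygous mice 9.30, from Olfr482 to Olfr510 on chromosome 7 (0 of 100). That last window begins and ends with olfactory receptor genes, a family lower in homozygous mice in 869 of 1027 genes. Shuffling gene order breaks up runs of related neighbours. The 0 of 100 there cannot tell an effect of this place from a shift of the family.

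Within batch 2, hepatocyte genes were compared between the older and the younger mice of each group. Among B6 controls they averaged 9.35 ± 1.56 (SD, log2, n = 4) at 63 days and 6.92 ± 0.24 (n = 4) at 61 days, a difference of 2.43 (exact permutation test, p = 0.0286, the smallest that 70 assignments allow, adjusted 0.0571 over both groups). Among homozygous mice they averaged 8.89 ± 0.62 (n = 4) at 57 days and 8.02 ± 1.01 (n = 4) at 52 days, a difference of 0.88 (exact permutation test, p = 0.20). In each group the numbers in the array names of the older mice come before those of the younger mice. Age and that order therefore cannot be told apart here.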
